A study of Mus musculus with 11 samples.

How the data were processed

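RNA was measured in 11 tumours grown from 4T1 cells in mice given vehicle, OPG-Fc, palbociclib or both drugs, by sequencing of poly(A) RNA. Per the submitters' processing notes, HISAT, Bowtie2 and RSEM were used, with no versions or roles given, on the builds GRCm39 and mm39. The authors deposited the values as FPKM, fragments scaled by transcript length and by the mapped fragments of the library, in 1 table of 17181 gene symbols and 11 libraries. Steps between the values were searched for whole reads and did not give any, so the read depth is unknown. The table holds no mitochondrial genes, and a list of these was therefore not tested. An annotation of the older build GRCm38 served only for transcript lengths and GC content, matched by gene symbol for 98.9% of the tested genes, so no coordinates are given.

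Values were taken as log2(FPKM + 1), and genes with an FPKM of at least 1 in at least 2 libraries were kept, which left 13074. All 11 libraries were fitted together by group with limma 3.58.1 in R 4.3.3, with a trend in the variance prior. The 8 comparisons were each treated group against vehicle, the combination against each single drug, each drug averaged over the other, and the interaction. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, and errors of fold changes are standard errors. Of 36 gene lists fixed before the data were examined, 35 could be tested with limma's camera at a preset correlation of 0.01, adjusted over the 35 lists, and again with the correlation estimated for each list. Members were also adjusted over the list alone. Groups, comparisons, lists, tests and the first set of alternatives were chosen before the data were examined.

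Genes were named by a rule fixed at the same time. It takes the 8 highest and 8 lowest passing genes of a comparison (4 and 4 for the averaged comparisons and the interaction), or the 3 smallest p in each direction where fewer than 3 passed. It also takes a panel of 13 genes of the RANK and CDK4/6 pathways, of which 12 are given for palbociclib against vehicle and the combination against palbociclib, and up to 4 members with the smallest p of each list described. Marker genes given as FPKM per library were chosen after their values were seen.

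No library was left out of the first fit. A second fit without vehicle replicate 2 is given beside it in each comparison. It was planned as 1 of the fits that leave out a library, and the choice to print it throughout was made after the values were seen. Settings fixed beforehand were varied 1 at a time: the pseudocount (0.1), the filter (no filter, or an FPKM of at least 5), the scaling, the variance prior, library weights, the libraries in the fit, the replicate number as a block, and each library in turn. Another 8 alternatives were chosen after seeing the data: corrections for transcript length and GC content by a natural spline with 5 degrees of freedom, the same corrections without vehicle replicate 2, leaving out libraries with lymphoid or skin transcripts, averaging libraries that share a number, and the settings fixed beforehand without vehicle replicate 2. The fit was tested on simulated data in which 200 of 13074 genes were changed. Of 100 genes changed by 1 on the log2 scale it recovered 37 for palbociclib against vehicle and 47 for the combination against OPG-Fc, and 53 and 87 without vehicle replicate 2, with 4 to 11 false calls. The simulated noise was independent between genes and libraries, and changed genes were picked among the more highly expressed. Shared differences in tissue content or length trend were not simulated, so recovery and false calls in these data may differ. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.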

Results

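Bulk poly(A) RNA sequencing was carried out on 11 tumours grown from 4T1 cells, a mouse mammary carcinoma line used as a model of triple-negative breast cancer. Cells were injected under the skin of both flanks, and treatment began when tumours reached about 100 mm3 and lasted 12 days. The groups were vehicle (n = 2), OPG-Fc at 10 mg/kg 3 times a week (n = 3), palbociclib at 30 mg/kg per day (n = 3) and the combination of both drugs (n = 3). OPG-Fc is a decoy receptor that binds RANKL, the ligand of RANK, and palbociclib is an inhibitor of the kinases CDK4 and CDK6. The deposited table held FPKM values for 17181 genes, and 13074 genes with an FPKM of at least 1 in at least 2 libraries were tested. The FPKM values of a library summed to between 576699 and 864670. The read depth is unknown, because the table holds no counts and the steps between its values did not give whole reads. The labels do not say which tumours came from 1 animal, so the p-values measure only the spread between these tumours. Column names of combination replicates 1 and 2 share their first number, as do those of OPG-Fc replicates 2 and 3, and the labels do not say what that number means. NSG hosts, which lack T, B and NK cells, are named in the labels, while the title calls the model syngeneic, so the source of lymphoid transcripts is not settled by the labels.

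Vehicle replicate 2 stood apart from the other 10 libraries. Epcam, an epithelial adhesion molecule, had an FPKM of 11.7 there against 336 to 604 in the others. Krt8, a keratin of simple epithelia, had an FPKM of 9.34 against 587 to 823. Lymphoid genes were high in the same library: Cd79a, part of the B cell receptor, had an FPKM of 723, Jchain, the joining chain of secreted antibodies, 3925, and Ccl21a, a chemokine of lymph node stroma, 1025. OPG-Fc replicate 2 came next, with an FPKM of 73.6 for Cd79a, 476 for Jchain and 177 for Ccl21a. The median FPKM of the epithelial and luminal genes was 1.83 in vehicle replicate 2 and 50.6 to 85.9 in the other 10, and the first principal component, which held 60.5% of the variance, set this library apart. Every comparison is therefore given with all 11 libraries and again without vehicle replicate 2, where the vehicle group is 1 library that is assumed to vary like the other groups.

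Other tissue transcripts also differed between libraries. Skin keratinocyte and hair follicle markers had a median FPKM of 48.7 and 31.1 in palbociclib replicates 1 and 3, against 0.42 in palbociclib replicate 2 and 0.055 to 5.54 elsewhere. Krt10, a keratin of differentiating epidermis, had an FPKM of 113 and 73.4 in those libraries and 1.74 in palbociclib replicate 2. Adipocyte markers had a median FPKM of 22.3 to 68.6 in the OPG-Fc libraries and 57.4 in vehicle replicate 2, against 3.45 in vehicle replicate 1, 1.33 to 2.53 with palbociclib and 3.28 to 21.8 with the combination. Ribosomal protein genes made up 20.4% to 33.9% of the summed FPKM, lowest in OPG-Fc replicate 1 and highest in combination replicate 3.

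**Figure D1:**
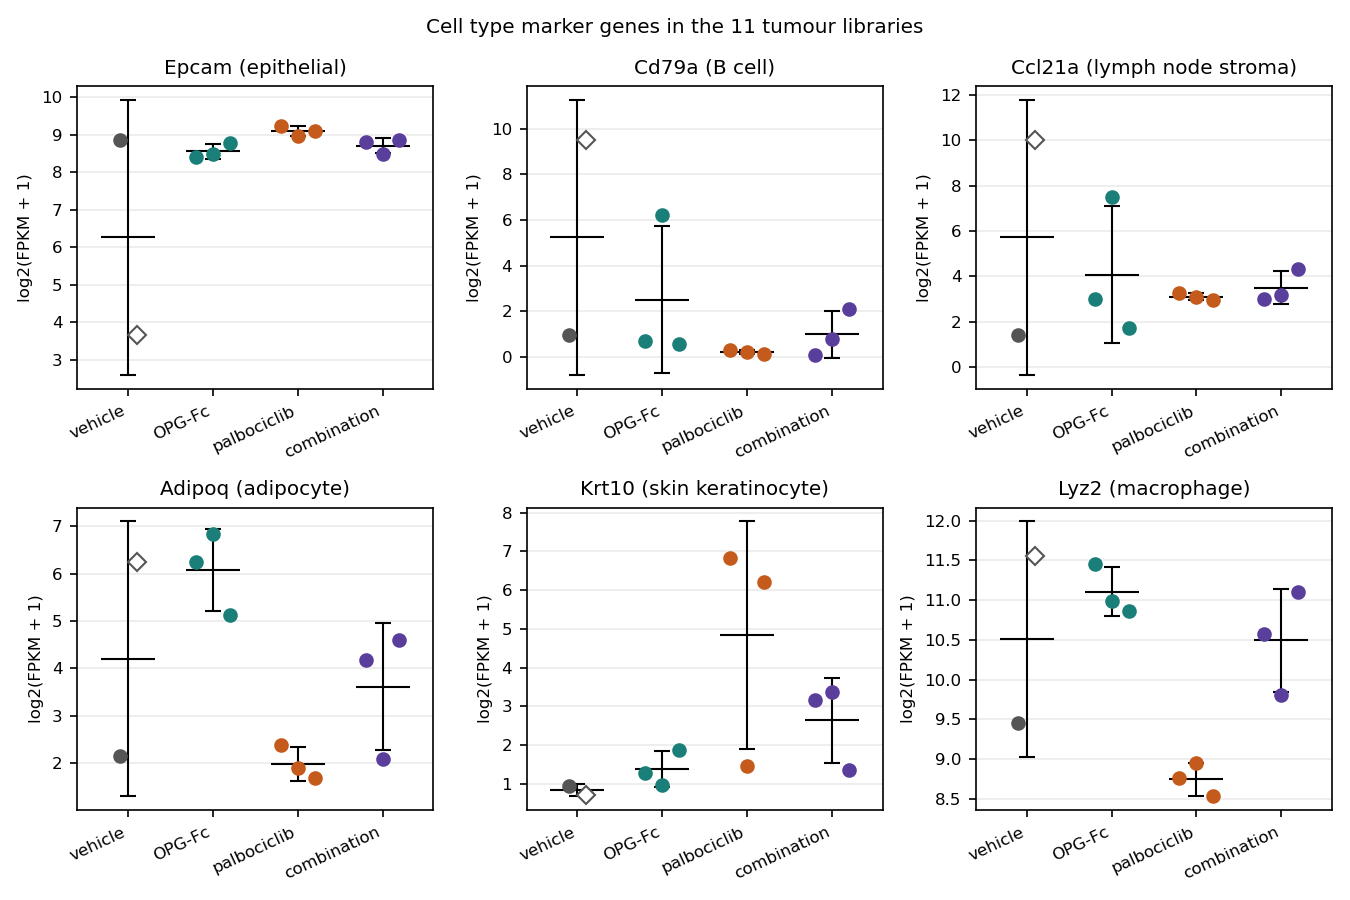
Expression of 6 cell type marker genes in the 11 tumour libraries, as log2(FPKM + 1) by group. Points are libraries, the open diamond is vehicle replicate 2, and bars show the mean and SD of each group (n = 2 for vehicle, n = 3 for the others); Epcam had an FPKM of 11.7 in vehicle replicate 2 and 336 to 604 in the other 10 libraries.

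Palbociclib was set against vehicle to show what CDK4/6 inhibition does to these tumours (n = 3 against n = 2, or 1 without vehicle replicate 2). Markers of vessels, fibroblasts and mitosis lay lower and ribosomal protein genes lay higher in palbociclib-treated tumours, but no single gene passed in limma. For the mitosis genes, palbociclib replicates 1 and 2 lay lower, with a mean log2(FPKM + 1) of 4.06 and 4.07. Palbociclib replicate 3, at 4.65, lay between vehicle replicates 1 and 2 (4.57 and 4.82). The 16 endothelial markers had a median log2 fold change of -0.56 with all 11 libraries and -0.34 without vehicle replicate 2. Among them, Kdr, the main VEGF receptor, was at -1.23 ± 0.26 and -0.78 ± 0.22, and Cdh5, the cadherin of endothelial junctions, at -0.84 ± 0.18 and -0.74 ± 0.21 (SE). The 21 fibroblast and collagen genes had medians of -0.41 and -0.74, with Fap, a protease of activated fibroblasts, at -1.08 ± 0.20 and -0.99 ± 0.23. The 39 ribosomal protein genes had medians of 0.57 and 0.67, with Rpl37 at 1.22 ± 0.24 and 0.99 ± 0.27.

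Over all genes, 0 genes passed in either fit; 3671 had an unadjusted p under 0.05 with all 11 libraries and 1266 without vehicle replicate 2. The genes with the smallest p among those higher were Avpi1 (2.03 ± 0.23, adjusted p = 0.055), Cracr2b, a regulator of store-operated calcium channels (1.48 ± 0.19, adjusted p = 0.0691), and Rpl39l, a ribosomal protein paralogue (1.55 ± 0.24, adjusted p = 0.147). Among those lower they were Timp3, an inhibitor of matrix metalloproteinases (-1.37 ± 0.17, adjusted p = 0.06), Aoc3, an amine oxidase of vessel walls and adipocytes (-1.55 ± 0.21, adjusted p = 0.081), and Sulf1, which edits heparan sulfate (-1.17 ± 0.17, adjusted p = 0.128). Without vehicle replicate 2 the list held Avpi1 (1.65 ± 0.20), Cracr2b (1.45 ± 0.23) and the desmosomal gene Pkp3 (0.96 ± 0.15) on the higher side. On the lower side it held the basement membrane collagen Col15a1 (-1.51 ± 0.16, adjusted p = 0.0515), Timp3 (-1.50 ± 0.19) and the collagen uptake receptor Mrc2 (-1.14 ± 0.17).

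The drug's own pathway showed no change that passed. Mki67, a marker of cycling cells, was at -1.23 ± 0.48 with all 11 libraries and -0.41 ± 0.42 without vehicle replicate 2. Ccnd1, the cyclin partner of CDK4 and CDK6, was at 2.07 ± 0.98 and -0.21 ± 0.26, and Rb1, the substrate of both kinases, at -1.07 ± 0.42 and -0.29 ± 0.33. Cdk4 was at 0.69 ± 0.28 and 0.29 ± 0.28, and Cdk6 at 0.21 ± 0.32 and -0.29 ± 0.30. Of the E-type cyclins, Ccne1 was at -0.61 ± 0.45 and 0.37 ± 0.21 and Ccne2 at -0.74 ± 0.38 and -0.41 ± 0.44. E2f1, a transcription factor released by phosphorylated RB, was at 0.23 ± 0.20 and -0.04 ± 0.19, and Cdkn1a, which encodes the inhibitor p21, at 0.40 ± 0.24 and 0.01 ± 0.20. Tnfrsf11a, which encodes RANK, was at -0.34 ± 0.25 and 0.07 ± 0.23, Tnfsf11, which encodes RANKL, at -0.21 ± 0.45 and 0.54 ± 0.40, and Tnfrsf11b, which encodes osteoprotegerin, at 1.11 ± 0.41 and 0.57 ± 0.42. Adjusted p over these 12 genes was lowest for Tnfrsf11b, at 0.159, with all 11 libraries and for Ccne1, at 0.57, without vehicle replicate 2.

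Of the 32 G2/M and mitosis genes, 0 passed over all genes or adjusted over the list alone, in either fit. Their medians were -0.48 and -0.37, with the mitotic kinase gene Plk1 at -0.81 ± 0.23 and -0.53 ± 0.25 and the mitotic cyclin gene Ccnb1 at -0.79 ± 0.23 and -0.45 ± 0.22. As a set they ranked below the other genes by limma's camera (adjusted p = 0.000202 and 0.000362; adjusted p = 0.624 and 0.767 with an estimated correlation), and the second median was -0.23 after correction for length and GC content. The 37 G1/S and E2F target genes had medians of -0.31 and -0.03 (camera adjusted p = 0.12 and 0.801; adjusted p = 0.785 and 0.942 with an estimated correlation). This list was called lower without palbociclib replicate 3 (-0.44, adjusted p = 0.00398) and without palbociclib replicates 1 and 3, which left 1 palbociclib library (-0.45, adjusted p = 0.0328). Gins2, a component of the replicative helicase, was at 0.81 ± 0.24 and 0.36 ± 0.18. Medians of the 18 genes of the CDK4/6-RB machinery were -0.16 and -0.07 (camera adjusted p = 0.321 and 0.398; adjusted p = 0.624 and 0.679 with an estimated correlation), and adjusted over the list alone 1 fell in the first fit, Rbl1, which encodes an RB relative (-0.78 ± 0.19). Those of the 14 RANK pathway components were -0.28 and 0.11 (camera adjusted p = 0.253 and 0.471; adjusted p = 0.785 and 0.905 with an estimated correlation). The 32 senescence-associated secretory genes turned from a median of 0.99 with all 11 libraries to -0.15 without vehicle replicate 2 (adjusted p = 0.0147 and 0.0116; adjusted p = 0.624 and 0.559 with an estimated correlation). Adjusted over the list alone, 0 of them passed in the first fit and 2 fell in the second, where the matrix protease gene Mmp9 was at -1.34 ± 0.24.

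Of the endothelial markers, 0 passed over all genes and 7 fell, adjusted over the list alone, with all 11 libraries; without vehicle replicate 2 0 passed. The set ranked below the other genes (camera adjusted p = 0.00184 and 0.000211; adjusted p = 0.624 and 0.349 with an estimated correlation). Its call ended without palbociclib replicates 1 and 3, at a median of -0.48 (adjusted p = 0.0519). Among the fibroblast and collagen genes 0 passed over all genes, and 2 and 9 fell adjusted over the list alone (camera adjusted p = 0.0147 and 2.97e-11; adjusted p = 0.624 and 0.349 with an estimated correlation). Lox, which crosslinks collagen, was at -1.82 ± 0.35 and Col1a2 at -1.31 ± 0.26 without vehicle replicate 2. Of the ribosomal protein genes 0 passed over all genes, while 20 and 0 rose adjusted over the list alone (camera adjusted p = 2.76e-10 and 1.34e-14; adjusted p = 0.624 and 0.543 with an estimated correlation). The share of ribosomal protein transcripts in a library goes with this set, and its median with all 11 libraries was 0.15 after quantile normalization.

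Markers of other tissues moved in the same comparison. The 10 skin keratinocyte and hair follicle markers had medians of 3.13 and 3.06 (camera adjusted p = 4.51e-05 and 1.16e-05; adjusted p = 0.624 and 0.543 with an estimated correlation), with the epidermal gene Dmkn at 5.21 ± 1.64 and Krt10 at 4.00 ± 1.33. These did not pass over all genes, and 10 and 0 rose adjusted over the list alone. The list went with palbociclib replicates 1 and 3, which carried those transcripts, and leaving out both, chosen for that reason, left 1 palbociclib library and a median of 0.40. The 18 epithelial and luminal genes had medians of 2.31 and 0.27 (camera adjusted p = 1.84e-06 and 0.00381; adjusted p = 0.624 and 0.349 with an estimated correlation), and the tight junction gene Cldn7 was at 3.01 ± 1.00 and 0.66 ± 0.26. The second median was 0.15 after correction for length and GC content. They did not pass over all genes in either fit, and 16 and 0 rose adjusted over the list alone. The 14 T, B and NK cell markers had medians of -2.52 and -0.40 (camera adjusted p = 0.00033 and 0.508; adjusted p = 0.624 and 0.932 with an estimated correlation). The T cell gene Cd8a was at -2.42 ± 0.99 and -0.68 ± 0.84, and 0 passed over all genes or adjusted over the list alone. Leaving out vehicle replicate 1, so that vehicle replicate 2 was the control, gave 6802 genes and medians of -0.26 for the fibroblast and collagen genes (adjusted p = 0.979), 4.63 for the epithelial and luminal genes, -4.76 for the T, B and NK cell markers and 2.12 for the senescence-associated secretory genes. Leaving out palbociclib replicate 2 gave 156 genes, and 185 without vehicle replicate 2. With all 11 libraries a pseudocount of 0.1 gave 1 gene and quantile normalization 3. These settings gave 5 and 1 without vehicle replicate 2, where the length correction gave 4, with GC content as well 7, an FPKM of at least 5 gave 3, median-of-ratios scaling 1 and array weights 1067.

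OPG-Fc was set against vehicle to show what RANKL blockade alone does (n = 3 against n = 2, or 1). Fibroblast genes lay higher in OPG-Fc tumours. So did skeletal muscle markers, at a median FPKM of 0.9 to 21.9 against 0.06 and 0.4 with vehicle. Vessel and adipocyte genes lay higher and interferon genes lower where vehicle replicate 1 was in the control; without it these medians were 0.31 (adjusted p = 0.391), -0.04 and 0.35. The interferon genes had a median FPKM of 32.6 in vehicle replicate 1, 15.1 in vehicle replicate 2 and values between these in the 3 OPG-Fc libraries. In the fit without vehicle replicate 2 the gene Cd300ld5, of a family of myeloid receptors, rose by 3.72 ± 0.36 on the log2 scale (adjusted p = 0.0223), with 1 vehicle library as the control. The 21 fibroblast and collagen genes had medians of 1.08 and 0.51, with Lum, which encodes the collagen-binding lumican, at 0.93 ± 0.16 and 1.02 ± 0.19. The 13 adipocyte markers had medians of 1.76 and 3.19, with Plin1, which coats lipid droplets, at 1.80 ± 0.70 and 3.12 ± 0.54, in libraries that also held adipocyte transcripts at a median FPKM of 22.3 to 68.6. The 16 endothelial markers had medians of 0.56 and 0.65, with the receptor gene Tie1 at 0.63 ± 0.19 and 0.87 ± 0.19, and the first median was 0.28 after correction for length and GC content.

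In the fit of all 11 libraries 0 genes passed in limma, and 1328 had an unadjusted p under 0.05. The smallest p belonged to Cracr2b (1.32 ± 0.19), the surface glycoprotein gene Cd99 (1.15 ± 0.18) and Dpep2, a dipeptidase (1.32 ± 0.23), on the higher side. On the lower side it belonged to the ubiquitin-conjugating enzyme gene Ube2h (-0.72 ± 0.17), the leukotriene receptor gene Cysltr2 (-0.77 ± 0.18) and Tbc1d1, a regulator of Rab GTPases (-0.55 ± 0.13), all at an adjusted p of 0.471. In the fit without vehicle replicate 2 Cd300ld5 was the 1 gene that passed, of 1632 with an unadjusted p under 0.05. It was followed by Lrg1, a secreted glycoprotein (2.60 ± 0.32, adjusted p = 0.0515), and Gprc5c (1.66 ± 0.21, adjusted p = 0.0515), with Ifi44, an interferon-induced gene (-1.27 ± 0.21, adjusted p = 0.0805), Tmem171 (-0.80 ± 0.16, adjusted p = 0.0879) and Egln3, an oxygen-sensing hydroxylase (-1.09 ± 0.23, adjusted p = 0.0977), on the lower side.

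Over all genes 0 members of these lists passed in either fit. Adjusted over the list alone, 10 and 8 fibroblast and collagen genes, 0 and 10 endothelial markers and 0 and 13 adipocyte markers rose. By limma's camera the fibroblast and collagen genes ranked above the other genes (adjusted p = 1.78e-10 and 5.63e-07; adjusted p = 0.197 and 0.337 with an estimated correlation). So did the endothelial markers (adjusted p = 8.69e-05 and 1.76e-07; adjusted p = 0.436 and 0.149 with an estimated correlation) and the adipocyte markers (adjusted p = 0.00105 and 3.22e-14; adjusted p = 0.758 and 0.149 with an estimated correlation). The 12 pericyte and smooth muscle markers had medians of 0.82 and 0.64, and 6 and 1 rose adjusted over the list alone (camera adjusted p = 0.000319 and 0.00106; adjusted p = 0.125 and 0.149 with an estimated correlation). The smooth muscle actin gene Acta2 was at 1.37 ± 0.37 in the first fit and the smooth muscle myosin gene Myh11 at 1.48 ± 0.30 in the second. Of the 17 macrophage markers, with medians of 0.35 and 0.88, 3 and 6 rose adjusted over the list alone (camera adjusted p = 0.0148 and 5.68e-09; adjusted p = 0.758 and 0.161 with an estimated correlation). Csf1r, the receptor for the macrophage growth factor CSF1, was at 1.11 ± 0.18 in the second fit. The 33 type I interferon response genes had medians of -0.12 and -0.55. Trim30a was at -0.82 ± 0.22 in the first fit and Oasl2 at -0.95 ± 0.25 in the second, and 0 and 1 fell adjusted over the list alone (camera adjusted p = 0.0216 and 1.29e-16; adjusted p = 0.758 and 0.161 with an estimated correlation). RANK pathway components had medians of -0.15 and 0.15 (camera adjusted p = 0.135 and 0.437; adjusted p = 0.758 and 0.915 with an estimated correlation). Tnfrsf11a was at 0.11 ± 0.25 and 0.52 ± 0.23.

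Which vehicle library served as the control decided most of this comparison. Leaving out vehicle replicate 1 gave 5272 genes, and a median of -0.17 for the macrophage markers, while the pericyte and smooth muscle markers had an adjusted p of 0.0827. The RANK pathway components were called lower in that fit, at -0.48 (adjusted p = 0.0456). The macrophage markers were at 0.22 after length correction. The interferon genes were at 0.02 without OPG-Fc replicate 1 (adjusted p = 0.187), -0.29 without OPG-Fc replicate 2, -0.24 after length correction, -0.23 after quantile normalization (adjusted p = 0.109), -0.18 after correction for length and GC content (adjusted p = 0.11) and -0.09 with the replicate number as a block (adjusted p = 0.0601). The 1 gene called without vehicle replicate 2 became 0 without OPG-Fc replicate 1 or palbociclib replicate 1, 10 without OPG-Fc replicate 3, and 83 and 51 without combination replicates 2 and 3. It also became 0 with no filter, with the replicate block and after correction for length, alone or with GC content, 5 with a pseudocount of 0.1, 41 with libraries that share a number averaged and 2536 with array weights.

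The combination was set against vehicle to show the joint effect of both drugs (n = 3 against n = 2, or 1). Without vehicle replicate 2, 6 genes rose and 2 fell. Among those that rose, H1f4 and H2bc12 are histone genes whose transcripts mostly lack a poly(A) tail (2.10 ± 0.28 and 1.91 ± 0.26), Cd99 encodes a surface glycoprotein (1.55 ± 0.20) and Mrpl12 a mitochondrial ribosomal protein (1.45 ± 0.19). Avpi1 rose by 1.51 ± 0.20 and Ubtd1 by 1.05 ± 0.14, while the basement membrane collagen Col15a1 fell by 1.47 ± 0.16 and the kinase gene Nuak1 by 1.10 ± 0.14, all at an adjusted p of 0.0452 and with 1 vehicle library as the control. The count of 8 went to 0 with no filter, median-of-ratios scaling, no variance trend, the replicate block and the averaged libraries, to 5 after length correction, to 18 with GC content as well, to 19 after quantile normalization, to 29 and 32 with an FPKM of at least 5 and a pseudocount of 0.1, and to 3136 with array weights. With all 11 libraries 0 genes passed, 3866 had an unadjusted p under 0.05 (3025 without vehicle replicate 2), and the smallest adjusted p was 0.0511. That 0 became 90 with an FPKM of at least 5, 13 with a pseudocount of 0.1 and 6 after quantile normalization. The smallest adjusted p was shared by Avpi1 (1.90 ± 0.23), H1f4 (1.94 ± 0.24) and Cd99 (1.38 ± 0.18) on the higher side, and by Tbc1d1 (-0.97 ± 0.13), the lipid transfer protein gene Pitpnc1 (-0.95 ± 0.14) and Ube2h (-1.09 ± 0.17) on the lower side. The direction of Nuak1 depended on the vehicle library, as it fell without vehicle replicate 2 and lay higher without vehicle replicate 1.

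The 39 ribosomal protein genes had medians of 0.75 and 0.76 against vehicle, with Rpl37 at 1.28 ± 0.24 and 1.05 ± 0.27 and Rps18 at 1.42 ± 0.27 and 1.31 ± 0.34. Over all genes 0 passed in either fit, and 31 and 27 rose adjusted over the list alone (camera adjusted p = 1.01e-13 and 1.25e-12; adjusted p = 0.895 and 0.88 with an estimated correlation). The 30 oxidative phosphorylation genes had medians of 0.43 and 0.64, with the complex I gene Ndufb9 at 1.52 ± 0.25 and 1.11 ± 0.23 and the complex IV gene Cox6c at 0.89 ± 0.16 and 0.87 ± 0.20. Of these 0 passed over all genes and 9 and 16 rose adjusted over the list alone (camera adjusted p = 0.000142 and 3.81e-08; adjusted p = 0.895 and 0.88 with an estimated correlation). The type I interferon response genes had a median of 0.06 and a mean of 0.10 with all 11 libraries, where camera placed them on the lower side (adjusted p = 0.924; adjusted p = 0.977 with an estimated correlation). Their median was -0.39 without vehicle replicate 2 (adjusted p = 0.000265; adjusted p = 0.88 with an estimated correlation), and Ifi44 was at -0.85 ± 0.21. Adjusted over the list alone 1 and 4 of the 33 fell, and 0 passed over all genes. After length correction the ribosomal medians were 0.45 and 0.47, and without vehicle replicate 2 the oxidative phosphorylation genes were at 0.31, or 0.26 with GC content as well. In the fit of all 11 libraries, quantile normalization left the ribosomal protein genes at 0.11 (adjusted p = 0.111) and the oxidative phosphorylation genes at 0.24 (adjusted p = 0.075), and the latter were at 0.13 after a correction for transcript length (adjusted p = 0.123) and at 0.31 without vehicle replicate 1 (adjusted p = 0.297). Leaving out vehicle replicate 1 gave 6640 genes; the 8 genes called without vehicle replicate 2 went to 0 without any 1 of the OPG-Fc libraries, the palbociclib libraries or combination replicate 1, and to 34 and 24 without combination replicates 2 and 3.

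The combination was set against palbociclib to show what OPG-Fc adds to the CDK4/6 inhibitor (n = 3 against n = 3). No gene passed in limma, while mitotic genes and macrophage markers lay higher in the combination. The 32 G2/M and mitosis genes had a median of 0.56, with Birc5, which encodes survivin, at 1.03 ± 0.22 and the phosphatase gene Cdc25c at 0.71 ± 0.16. The 17 macrophage markers had a median of 0.89, with the folate receptor gene Folr2 at 2.61 ± 0.67, Lyz2, which encodes lysozyme, at 1.75 ± 0.49, and the complement gene C1qc at 1.00 ± 0.28. Lyz2 had an FPKM of 896 to 2195 against 368 to 491 with palbociclib.

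With all 11 libraries 883 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.637; without vehicle replicate 2, which changes the error but not the fold, these were 2318 and 0.0543. The smallest p with all 11 libraries belonged to the histone genes H3c3 (1.32 ± 0.23) and H2ac6 (1.40 ± 0.25), the Fc receptor gene Fcgr3 (0.94 ± 0.17), the Notch receptor gene Notch3 (-0.93 ± 0.23), the cornified envelope gene Sprr2h (-1.98 ± 0.50) and the myosin gene Myo18a (-0.66 ± 0.17). In the other fit it belonged to Alox5ap, needed for leukotriene synthesis (1.54 ± 0.18), Ms4a8a (2.10 ± 0.29), Renbp (0.83 ± 0.12), Nuak1 (-0.77 ± 0.10), the myosin gene Myh14 (-1.22 ± 0.16) and the guidance cue gene Ntn1 (-1.09 ± 0.16), all at an adjusted p of 0.0543. Leaving out palbociclib replicate 2, the palbociclib library with few skin transcripts, gave 143 genes with the other 10 libraries and 374 without vehicle replicate 2, where leaving out combination replicate 2 gave 155. Array weights gave 671 genes with all 11 libraries and 738 without vehicle replicate 2, where an FPKM of at least 5 gave 53 and the length and GC correction 41.

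The 12 genes of the RANK and CDK4/6 panel given here did not pass. Tnfrsf11a was at 0.29 ± 0.23, Tnfsf11 at 0.00 ± 0.40 and Tnfrsf11b at -0.47 ± 0.37. Ccnd1 was at -0.28 ± 0.87, Cdk4 at 0.25 ± 0.25, Cdk6 at -0.48 ± 0.29 and Rb1 at 0.06 ± 0.38. The cyclin genes Ccne1 and Ccne2 were at 0.44 ± 0.40 and 0.05 ± 0.34, E2f1 at 0.09 ± 0.18, Cdkn1a at 0.32 ± 0.21 and Mki67 at 0.35 ± 0.43, with the lowest adjusted p at 0.743 for Cdk6 (0.2 for Ccne1 without vehicle replicate 2). The CDK4/6-RB machinery had a median of 0.08 (camera adjusted p = 0.689 and 0.649; adjusted p = 0.989 and 0.87 with an estimated correlation) and the RANK pathway components one of -0.09 (camera adjusted p = 0.636 and 0.679; adjusted p = 0.989 and 0.969 with an estimated correlation). Adjusted over the list alone, 0 passed with all 11 libraries, and 1 of each list rose without vehicle replicate 2. In the first list Cdkn2d, which encodes a CDK4/6 inhibitor, rose by 0.80 ± 0.13 in that fit, and in the second Relb, an NF-kB subunit, by 0.55 ± 0.14.

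Of the G2/M and mitosis genes 0 passed over all genes, and 13 rose adjusted over the list alone (17 without vehicle replicate 2; camera adjusted p = 6.76e-17 and 6.05e-12; adjusted p = 0.865 and 0.799 with an estimated correlation). Of the macrophage markers 0 passed over all genes and 9 rose adjusted over the list alone (14 without vehicle replicate 2; camera adjusted p = 2.39e-11 and 7.05e-11; adjusted p = 0.865 and 0.362 with an estimated correlation). The 37 G1/S and E2F target genes had a median of 0.20. The thymidine kinase gene Tk1 was at 0.62 ± 0.24, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00129 and 0.00139; adjusted p = 0.981 and 0.87 with an estimated correlation). The 33 type I interferon response genes had a median of -0.31. Oas3, an antiviral sensor, was at -0.82 ± 0.32, and 0 passed in the same way (camera adjusted p = 5.18e-05 and 1.73e-05; adjusted p = 0.981 and 0.799 with an estimated correlation). Adipocyte markers had a median of 0.87. Fabp4, a fatty acid carrier, was at 1.65 ± 0.84, and 0 passed over all genes, while 0 and 4 rose adjusted over the list alone (camera adjusted p = 0.00317 and 0.00036; adjusted p = 0.981 and 0.799 with an estimated correlation).

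The 13 basal keratinocyte and myoepithelial genes had a median of -1.25, with the keratin gene Krt16 at -4.07 ± 1.42 (camera adjusted p = 5.74e-06 and 6.81e-06; adjusted p = 0.865 and 0.799 with an estimated correlation). The 10 skin keratinocyte and hair follicle markers had a median of -1.88, with Lor, a protein of the cornified envelope, at -1.79 ± 0.69 (camera adjusted p = 5.74e-06 and 0.000482; adjusted p = 0.865 and 0.799 with an estimated correlation). Members of either list that passed numbered 0, over all genes and adjusted over the list alone. Skin transcripts lay in palbociclib replicates 1 and 3, and leaving out both, chosen for that reason, left 1 palbociclib library and medians of 0.01 and 1.16. The G1/S genes lost their call without palbociclib replicate 1 (0.12, adjusted p = 0.0574), palbociclib replicate 2 (0.11, adjusted p = 0.0776) or combination replicate 1 (0.06, adjusted p = 0.352) and were at 0.34 without palbociclib replicate 3. The interferon genes were at -0.17 without palbociclib replicate 1, the skin list at -1.22 and -3.18 without palbociclib replicates 1 and 2, and the adipocyte markers at 1.36 with a pseudocount of 0.1.

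The combination was set against OPG-Fc to show what the CDK4/6 inhibitor adds to RANKL blockade (n = 3 against n = 3), and here genes passed with all 11 libraries. Of the 13 that passed, 12 fell. Col3a1, a fibrillar collagen, fell by 1.79 ± 0.23 on the log2 scale (adjusted p = 0.0377), from an FPKM of 614 to 983 with OPG-Fc to 197 to 279 with the combination. Cdh5 fell by 1.36 ± 0.17 (adjusted p = 0.0377), from an FPKM of 21.0 to 30.7 to one of 7.91 to 10.1. The linker histone gene H1f4, whose transcripts mostly lack a poly(A) tail, was the 1 gene that rose (1.68 ± 0.21, adjusted p = 0.0377).

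The comparison held 2020 genes that had an unadjusted p under 0.05. Besides Col3a1 and Cdh5, those with the lowest fold changes were Aoc3 (-1.71 ± 0.19), Col15a1 (-1.70 ± 0.24), the fibrillin gene Fbn1 (-1.50 ± 0.21), the basement membrane gene Nid1 (-1.42 ± 0.19), the laminin gene Lama4 (-1.34 ± 0.19) and the fibulin gene Fbln1 (-1.33 ± 0.17). Without vehicle replicate 2, which does not enter these folds but changes their error, 615 genes passed, 129 higher and 486 lower, the 13 among them. The highest of these were histone genes, with H1f4 (1.68 ± 0.20), H2bc23 and H2bc24 (1.62 ± 0.25 each), H4c6 (1.62 ± 0.36), H4c4 (1.61 ± 0.30), H1f3 (1.40 ± 0.24), H3c13 (1.38 ± 0.32) and H4c2 (1.28 ± 0.19). The lowest, in a comparison where adipocyte transcripts were high in the OPG-Fc libraries, were Thrsp, which promotes lipogenesis (-4.08 ± 0.93), Cyp2e1 (-3.27 ± 0.73), the carboxylesterase gene Ces1d (-3.07 ± 0.43), Pck1, which starts gluconeogenesis (-2.64 ± 0.49), the desaturase gene Scd1 (-2.58 ± 0.46), Gpd1 (-2.49 ± 0.51) and the lipoprotein lipase gene Lpl (-2.43 ± 0.32), and the eosinophil ribonuclease gene Ear2 (-2.52 ± 0.57).

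The 21 fibroblast and collagen genes had a median of -1.10. Of these 2 fell over all genes and 16 adjusted over the list alone (16 and 20 without vehicle replicate 2). Col6a2 was at -1.22 ± 0.20 and Fap at -1.09 ± 0.18, and in the second fit Col1a2 (-1.65 ± 0.18) and Col1a1 (-1.50 ± 0.18) fell (camera adjusted p = 1.24e-13 and 8.33e-14; adjusted p = 0.0737 and 0.236 with an estimated correlation). Endothelial markers had a median of -0.93. Of them 1 of 16 fell over all genes and 10 adjusted over the list alone (10 and 10 without vehicle replicate 2, where Pecam1, an adhesion molecule of endothelial junctions, fell by 1.00 ± 0.11). Their camera adjusted p was 1.65e-10 and 7.53e-09 (adjusted p = 0.0737 and 0.18 with an estimated correlation). Pericyte and smooth muscle markers had a median of -0.93. Here 0 of 12 passed over all genes and 8 fell adjusted over the list alone (8 and 8 without vehicle replicate 2), with the pericyte gene Rgs5 at -1.37 ± 0.25. This was the 1 list whose call held with an estimated correlation, with all 11 libraries (camera adjusted p = 7.63e-06 and 2.33e-05; adjusted p = 0.047 and 0.154 with an estimated correlation), and its median was -0.61 in both fits after length correction. The 13 adipocyte markers had a median of -2.04. Of these 0 passed over all genes and 3 fell adjusted over the list alone (5 and 11 without vehicle replicate 2, where the adipogenic factor gene Pparg fell by 1.53 ± 0.27). Camera gave adjusted p of 9.05e-06 and 1.32e-06 (adjusted p = 0.782 and 0.519 with an estimated correlation). Adipocyte transcripts had a median FPKM of 22.3 to 68.6 in the OPG-Fc libraries.

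Of the 39 ribosomal protein genes, with a median of 0.68, 0 passed over all genes and 38 rose adjusted over the list alone (1 and 38 without vehicle replicate 2, where Rpl6 rose by 0.78 ± 0.19). Their camera adjusted p were 1.83e-26 and 9.23e-19 (adjusted p = 0.447 and 0.574 with an estimated correlation). The 30 oxidative phosphorylation genes had a median of 0.37. Of these 0 passed over all genes or adjusted over the list alone with all 11 libraries (1 and 6 rose without vehicle replicate 2, where Ndufb9 rose by 0.72 ± 0.16). Camera gave adjusted p of 1.22e-09 and 4.44e-08 (adjusted p = 0.596 and 0.688 with an estimated correlation). Long transcripts ranked relatively lower in the combination libraries, where the Spearman correlation of each gene's deviation with its length was -0.54 to -0.23, against 0.10 to 0.38 with OPG-Fc. After quantile normalization the ribosomal protein genes were at 0.11 and the oxidative phosphorylation genes at 0.15. The latter were at 0.24 without combination replicate 3, and at 0.22 and 0.21 after length correction in the 2 fits. The 13 genes went to 0 when any 1 of the 9 treated libraries or both palbociclib libraries with skin transcripts were left out, when libraries that share a number were averaged, and after a correction for transcript length, alone or with GC content. They also went to 0 with a pseudocount of 0.1, no filter, median-of-ratios scaling, quantile normalization and the replicate block, to 160 with only the groups compared, to 116 without both libraries with lymphoid transcripts and to 3490 with array weights. The 615 genes went to 23 without OPG-Fc replicate 1, 56 without combination replicate 2, 116 without OPG-Fc replicate 2 and 219 to 394 without each of OPG-Fc replicate 3, palbociclib replicates 1 and 3 and combination replicates 1 and 3, to 89 with the averaged libraries, 203 with the replicate block, 284 after quantile normalization, 402 with an FPKM of at least 5, 314 after the length correction, 3844 with array weights and 153 without both palbociclib libraries with skin transcripts.

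**Figure D2:**
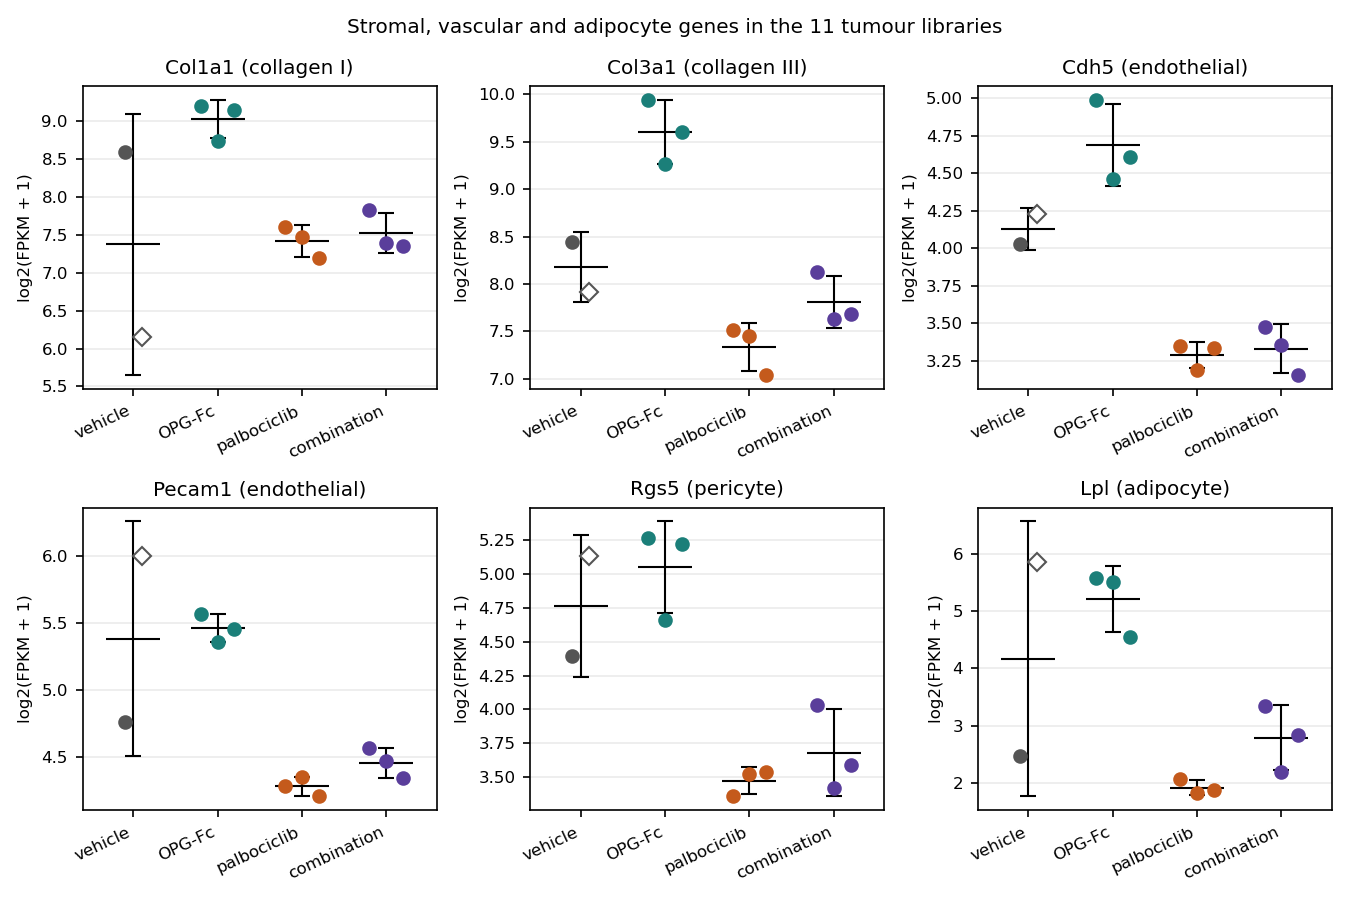
Expression of collagen, endothelial, pericyte and adipocyte genes in the 11 tumour libraries, as log2(FPKM + 1) by group. Points are libraries, the open diamond is vehicle replicate 2, and bars show the mean and SD of each group (n = 2 for vehicle, n = 3 for the others); Col3a1 had an FPKM of 614 to 983 with OPG-Fc and 131 to 279 in the palbociclib and combination libraries.

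Palbociclib was next averaged over the arms with and without OPG-Fc (6 libraries against 5, or 4 without vehicle replicate 2). Group means were weighted equally, so without vehicle replicate 2 vehicle replicate 1 alone counted as much as the OPG-Fc group. Of 16 endothelial markers 10 fell with all 11 libraries and 9 without vehicle replicate 2, and 13 and 7 of 39 ribosomal protein genes rose. Cdh5 fell by 1.10 ± 0.12 with all 11 libraries (adjusted p = 0.0142) and by 1.05 ± 0.13 without vehicle replicate 2 (adjusted p = 0.00748). Col3a1 fell by 1.32 ± 0.18 and 1.45 ± 0.18 (adjusted p = 0.0247 and 0.00734). Rpl37 rose by 0.95 ± 0.16 and 0.83 ± 0.17 (adjusted p = 0.0381 and 0.0339).

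In the fit of all 11 libraries 370 genes passed, 180 higher and 190 lower, and 511 passed without vehicle replicate 2, 213 higher and 298 lower, with 263 in both. The 370 went to 60 after length correction, 195 with GC content as well, 7 with the replicate block, 0 with array weights, 221 with no filter, 181 after median-of-ratios scaling and 184 after quantile normalization. The 511 went to 33 with the replicate block and 3825 with array weights. Long transcripts ranked lower in some of the libraries with palbociclib. The Spearman correlation of each gene's deviation with its length was -0.54 to 0.19 in the 6 libraries with palbociclib and 0.08 to 0.38 in the other 5. The highest in the first fit were the myoglobin gene Mb (1.99 ± 0.42), the transcription factor gene Cebpb (1.77 ± 0.32), Arhgdig (1.61 ± 0.31) and Klc3 (1.58 ± 0.32). The lowest were the Wnt antagonist gene Sfrp4 (-2.23 ± 0.48), the complement genes C4b (-2.15 ± 0.40) and C6 (-1.84 ± 0.33) and Itih5, a matrix protein gene (-1.88 ± 0.34). Mb is 1 of the skeletal muscle markers, whose median FPKM was 0.06 and 0.4 in the vehicle libraries and 0.9 to 21.9 in the treated ones. In the second fit the highest were H1f4 (1.43 ± 0.17), Rps27rt (1.42 ± 0.32), H2bc23 and H2bc24 (1.41 ± 0.22 each), and the lowest C4b (-1.72 ± 0.37), Ces1d (-1.61 ± 0.37), Col15a1 (-1.61 ± 0.10) and Aoc3 (-1.56 ± 0.15).

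Endothelial markers had medians of -0.78 and -0.63. Of these 10 and 9 of 16 fell over all genes and 10 and 11 adjusted over the list alone, with Kdr at -1.27 ± 0.18 and -1.05 ± 0.13 (camera adjusted p = 2.89e-06 and 9.22e-08; adjusted p = 0.33 and 0.165 with an estimated correlation). Fibroblast and collagen genes had medians of -0.73 and -0.94. Of these 6 and 14 of 21 fell over all genes and 13 and 21 adjusted over the list alone, with Fap at -1.09 ± 0.13 in the first fit and Col1a1 at -1.34 ± 0.15 in the second (camera adjusted p = 4.3e-07 and 3.77e-14; adjusted p = 0.33 and 0.168 with an estimated correlation). Pericyte and smooth muscle markers had medians of -0.46 and -0.52. Of these 2 and 5 of 12 fell over all genes and 4 and 8 adjusted over the list alone, where 1 rose without vehicle replicate 2, and Rgs5 fell by 1.33 ± 0.18 and 1.15 ± 0.17 (camera adjusted p = 0.00388 and 0.000137; adjusted p = 0.33 and 0.165 with an estimated correlation). Adipocyte markers had medians of -1.83 and -0.91. Of these 0 and 1 of 13 fell over all genes and 11 and 3 adjusted over the list alone, with Lpl at -2.34 ± 0.54 and -1.49 ± 0.28 (camera adjusted p = 0.000213 and 0.00283; adjusted p = 0.642 and 0.752 with an estimated correlation). Ribosomal protein genes had medians of 0.64 and 0.62. Of these 13 and 7 of 39 rose over all genes and 37 and 39 adjusted over the list alone (camera adjusted p = 3.62e-19 and 8.16e-20; adjusted p = 0.642 and 0.624 with an estimated correlation). The ribosomal share of the summed FPKM was 26.7% to 33.9% in the 6 libraries with palbociclib and 20.4% to 23.5% in the other 5, and after quantile normalization, which gives all libraries 1 distribution and so removes a rise shared by genes of the highest values, the median was 0.14. Averaging the libraries that share a number took the 370 genes to 0 and the 511 to 114, and leaving out both palbociclib libraries with skin transcripts took them to 0 and 3. Leaving out any 1 treated library but palbociclib replicate 2 took the 370 genes to between 2 and 33, leaving out vehicle replicate 1 took them to 6927, and the 511 went to between 112 and 217 without each of the OPG-Fc libraries, palbociclib replicates 1 and 3 and combination replicate 2. Pericyte genes were at -0.31 (adjusted p = 0.109) and adipocyte markers at -2.75 without vehicle replicate 1.

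OPG-Fc was averaged over the arms with and without palbociclib (6 libraries against 5, or 4). Here vehicle replicate 1 alone counted as much as the palbociclib group in the fit without vehicle replicate 2. Without vehicle replicate 2, 11 of 13 adipocyte and 7 of 17 macrophage markers rose, and 4 of 33 type I interferon response genes and 4 of 28 hypoxia and glycolysis genes fell. Lpl rose by 1.81 ± 0.28 (adjusted p = 0.015), Csf1r by 0.84 ± 0.11 (adjusted p = 0.0109), and the small leucine-rich proteoglycan gene Lum by 0.78 ± 0.12 (adjusted p = 0.0144). Ifi44 fell by 0.82 ± 0.13 (adjusted p = 0.015) and Ndrg1, a hypoxia-induced gene, by 0.79 ± 0.15 (adjusted p = 0.0254). In that fit 452 genes passed, 414 higher and 38 lower. This count was 136 with the replicate block, 283 with no filter, 310 with libraries that share a number averaged and 3136 with array weights. With all 11 libraries 0 genes passed, and 1376 had an unadjusted p under 0.05; without both libraries with lymphoid transcripts 216 passed.

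The highest of the 452 genes were Thrsp (3.82 ± 0.81), the adipokine gene Retn (3.44 ± 0.72), Cyp2e1 (3.34 ± 0.63) and Cfd, which encodes adipsin (3.13 ± 0.69), and the lowest Oas3 (-0.88 ± 0.19), the desmosomal gene Perp (-0.87 ± 0.17), Ddx60 (-0.82 ± 0.19) and Ifi44. In the first fit the smallest p belonged to Dpep2 (1.15 ± 0.15), Lum (0.73 ± 0.11), the Wnt modulator gene Sfrp2 (1.53 ± 0.24), Bcl2l11, which encodes the apoptosis factor BIM (-0.48 ± 0.09), Ube2h (-0.56 ± 0.12) and Foxn3 (-0.45 ± 0.10), at adjusted p of 0.189 to 0.246. The direction of Perp depended on the vehicle library, as it lay lower without vehicle replicate 2 and higher without vehicle replicate 1.

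Adipocyte markers had medians of 1.29 and 1.95, and 0 and 11 of 13 rose over all genes and 0 and 11 adjusted over the list alone, with Fabp4 at 1.88 ± 0.63 and 2.73 ± 0.47 (camera adjusted p = 3.9e-05 and 2.16e-10; adjusted p = 0.747 and 0.211 with an estimated correlation). Macrophage markers had medians of 0.60 and 0.81, and 0 and 7 of 17 rose over all genes and 12 and 15 adjusted over the list alone, with Folr2 at 1.90 ± 0.50 and 2.58 ± 0.37 (camera adjusted p = 1.34e-08 and 2.34e-11; adjusted p = 0.418 and 0.211 with an estimated correlation). Fibroblast and collagen genes had medians of 0.71 and 0.29. Of these 0 and 6 of 21 rose over all genes and 7 and 10 adjusted over the list alone (camera adjusted p = 1.58e-10 and 1.07e-05; adjusted p = 0.195 and 0.46 with an estimated correlation). G2/M and mitosis genes had medians of 0.34 and 0.46. Of these 0 and 1 of 32 rose over all genes, namely Cdc20, an activator of the anaphase-promoting complex (0.77 ± 0.14), and 10 and 11 adjusted over the list alone (camera adjusted p = 5.26e-09 and 1.37e-07; adjusted p = 0.747 and 0.84 with an estimated correlation). Type I interferon response genes had medians of -0.22 and -0.41. Of these 0 and 4 of 33 fell over all genes, and adjusted over the list alone 0 passed in the first fit and 20 fell and 1 rose in the second (camera adjusted p = 3.9e-05 and 2.46e-13; adjusted p = 0.747 and 0.211 with an estimated correlation). Hypoxia and glycolysis genes turned from a median of 0.17 to -0.31. Of these 0 and 4 of 28 fell over all genes, and adjusted over the list alone 0 passed in the first fit and 11 fell and 1 rose in the second (camera adjusted p = 0.222 and 6.76e-08; adjusted p = 0.82 and 0.211 with an estimated correlation). Leaving out vehicle replicate 1 gave 4012 genes, and the medians of the adipocyte markers and interferon genes were 0.63 (adjusted p = 0.379) and 0.02 (adjusted p = 0.962), and the hypoxia and glycolysis genes were called higher at 0.60 (adjusted p = 6.32e-08). The 452 genes numbered 110 to 277 without each of the OPG-Fc libraries, palbociclib replicates 1 and 3 and combination replicate 1, and 0 without both palbociclib libraries with skin transcripts; with all other libraries, 79 genes passed without palbociclib replicate 2.

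**Figure D3:**
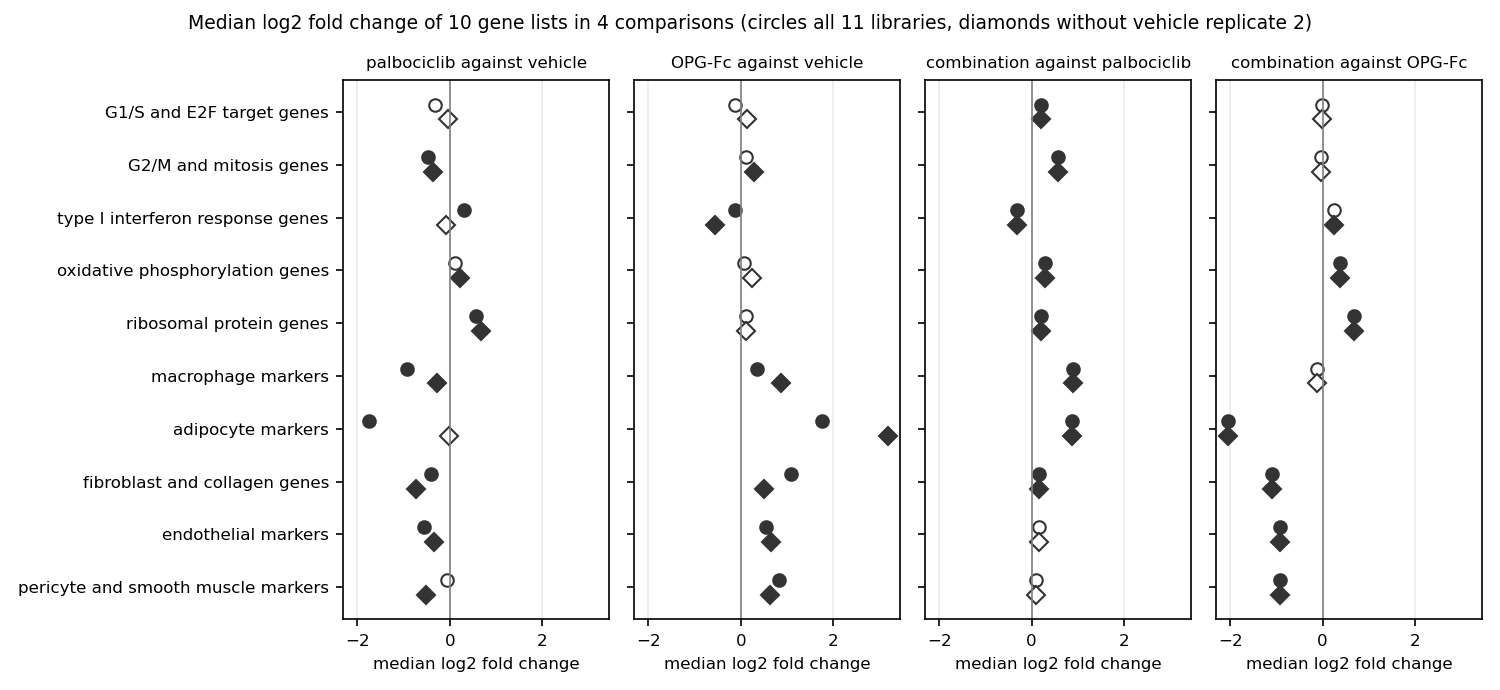
Median log2 fold change of 10 gene lists in 4 comparisons. Circles are from all 11 libraries and diamonds from the fit without vehicle replicate 2, and filled symbols have a camera adjusted p under 0.05 with the preset correlation; the fibroblast and collagen genes were at -1.10 in the combination against OPG-Fc in both fits.

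The interaction asks whether palbociclib acted differently in tumours given OPG-Fc, with all 4 groups in the test. No gene passed: 709 had an unadjusted p under 0.05 with all 11 libraries and 633 without vehicle replicate 2, and the smallest adjusted p were 0.647 and 0.951. As sets, mitotic genes had a higher and vessel and fibroblast genes a lower difference with OPG-Fc than without it. The G2/M and mitosis genes had a median interaction of 0.49 and 0.34, with the kinase gene Aurka at 0.92 ± 0.32 and 0.77 ± 0.35 (camera adjusted p = 7.55e-06 and 8.61e-06; adjusted p = 0.729 and 0.748 with an estimated correlation). Endothelial markers were at -0.29 and -0.51, with Vwf, which encodes a clotting factor of endothelium, at -0.63 ± 0.28 and -0.90 ± 0.25 (camera adjusted p = 0.0149 and 1.03e-05; adjusted p = 0.729 and 0.53 with an estimated correlation). Fibroblast and collagen genes were at -0.67 and -0.43, with Fbln1 at -0.92 ± 0.26 and -0.81 ± 0.28 (camera adjusted p = 0.000133 and 0.00247; adjusted p = 0.729 and 0.748 with an estimated correlation). Their medians were -0.45 and -0.30 after length correction, the second -0.21 with GC content as well, and the first -1.04 without vehicle replicate 1. Adipocyte markers were at -0.24 and -1.91, with Plin1 at -1.03 ± 0.94 and -2.35 ± 0.66 (camera adjusted p = 0.454 and 5.73e-09; adjusted p = 0.924 and 0.552 with an estimated correlation). Skin keratinocyte and hair follicle markers were at -2.31 and -2.32, with Sbsn at -3.04 ± 1.52 and -2.86 ± 1.74 (camera adjusted p = 0.00145 and 0.00585; adjusted p = 0.729 and 0.748 with an estimated correlation), and their median was 0.41 without the 2 palbociclib libraries that held skin transcripts, left out for that reason.

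Over all genes 0 members of these lists passed. Adjusted over the list alone, 2 endothelial and 5 adipocyte markers fell without vehicle replicate 2, and 0 of the G2/M, fibroblast and skin genes passed in either fit. Single genes with the smallest p were Praf2 (1.02 ± 0.20), Ppp1ccb (1.30 ± 0.30), H3c3 (1.39 ± 0.35), Cracr2b (-1.50 ± 0.26), Avpi1 (-1.35 ± 0.31) and the heat shock gene Hspa1a (-1.84 ± 0.43) with all 11 libraries. In the other fit they were Tmem171 (1.14 ± 0.20), Plp2 (0.96 ± 0.20), Pigf (0.77 ± 0.17), the lactoferrin gene Ltf (-2.68 ± 0.50), Cracr2b (-1.47 ± 0.28) and Cd300ld5 (-2.31 ± 0.45). The endothelial list lost its call without vehicle replicate 1 (-0.19, adjusted p = 0.71), OPG-Fc replicate 1 (-0.23, adjusted p = 0.0612) or palbociclib replicate 2 (-0.29, adjusted p = 0.0786) and after correction for length and GC content (-0.15, adjusted p = 0.0899), and the skin list without vehicle replicate 1 (adjusted p = 0.175), whose median was -1.42 and -3.78 without palbociclib replicates 1 and 2. Length correction alone left the endothelial list at -0.18 (adjusted p = 0.0257). Leaving out vehicle replicate 1 gave 4800 genes, and palbociclib replicate 2 61 genes.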

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

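The tests on vehicle replicate 2 and the comparison of macrophage with fibroblast genes were chosen only after the result was seen. The length and GC corrections and the fat covariate were added after the data were seen, with their expected values written before their results.

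Whether the palbociclib effect on a gene list differed between tumours with and without OPG-Fc was asked by a test of the difference itself. Camera at the preset correlation called 15 of 35 lists with all 11 libraries. In either fit only the called lists described above are given, with their median interaction. With all 11 libraries it was 0.491 for the G2/M and mitosis genes, -0.29 for the endothelial markers, -0.67 for the fibroblast and collagen genes and -2.312 for the skin keratinocyte and hair follicle markers. In the fit without vehicle replicate 2 it was 0.337 for the G2/M and mitosis genes, -1.913 for the adipocyte markers, -0.507 for the endothelial markers, -0.429 for the fibroblast and collagen genes and -2.318 for the skin markers. With an estimated correlation the lowest adjusted p among these was 0.53, so the calls rest on the preset correlation.

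Vehicle replicate 2 had lymphoid transcripts and few tumour transcripts. A swap with another library of this series cannot be told apart, since its partner would be a tumour library under another label, and the groups do not separate well enough to find one: 2 of the 9 treated libraries correlated most with a library of another group, and 0 with vehicle replicate 1. The labels name NSG hosts and the title a syngeneic model. Hosts without Il2rg transcript were argued against for vehicle replicate 2, whose Il2rg FPKM of 237.53 lay above that of the other 10 libraries while its epithelial and luminal genes were low. In the other 10, at 11.4 or more, this cannot be told apart from Il2rg transcript of the tumour cells, as no table separates host from tumour. Lymphoid tissue in the sequenced piece is a candidate explanation. In this library 10 of 14 T, B and NK cell markers were at least 5 times above the highest of the other 10 libraries. That count restates the pattern and does not test the explanation. A sample from outside this series was not tested, and no biological explanation was tested.

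Fibroblast and collagen genes were lower in the combination than with OPG-Fc, by a median of -1.096 (-1.321 to -1.038 as single libraries were left out), without vehicle replicate 2. Transcript length as the whole cause was argued against, since the median after correction was -0.933 (-1.062 to -0.848). A lower share of all host cells alike was argued against, since macrophage markers lay 0.98 above the fibroblast genes (0.617 to 1.249). Fat tissue in the OPG-Fc pieces as the source stays open. With the adipocyte score as covariate the median was -1.342 (-1.76 to -0.788). This cannot decide, since the scores did not overlap between OPG-Fc (4.621 to 5.929) and the combination (2.549 to 3.988). An effect of palbociclib on stroma and a difference in the pieces taken may both explain it, and neither was tested.

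Ribosomal protein genes were higher with palbociclib, by a median of 0.624 (0.562 to 0.687) without vehicle replicate 2. Transcript length as the whole cause was argued against by a median of 0.493 after correction (0.454 to 0.542), and length with GC content by one of 0.52 (0.448 to 0.576). Quantile normalization of all 11 libraries, which gives each library the same distribution of values, left a median of 0.14. It removes by construction a rise shared by genes that hold 20.4% to 33.9% of the summed FPKM, so it decides nothing. A difference in the composition of the libraries and a drug effect on these genes both stay open.

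Splits of the libraries into other groups of the same sizes were counted for 4 comparisons, with each tumour taken as independent, although some column names share a number. For the combination against palbociclib the real split gave 0 genes, so 10 of 10 splits gave as many by construction (highest other 1), in both fits. For the combination against OPG-Fc it was 1 of 10 in both fits, with 13 and 615 genes in the real split and 0 in the highest other. In both comparisons 10 splits are too few for a share under 0.05. For palbociclib averaged over OPG-Fc 1 of 100 splits gave as many with all 11 libraries (370, highest other 140). It was 1 of 80 without vehicle replicate 2 (511, highest other 3), a fit printed throughout after the values were seen. Both shares lie under 0.05, which argues against chance for independent tumours only and does not exclude it. Averaging the libraries that share a number took the 370 and 511 genes to 0 and 114, which leaves open what tumours of 1 animal would give. For OPG-Fc averaged over palbociclib the real split gave 0 genes with all 11 libraries, so 100 of 100 gave as many by construction (highest other 2). It was 1 of 80 without vehicle replicate 2 (452, highest other 152). That share lies under 0.05 under the same condition and does not exclude chance. The count of 452 rests on 1 vehicle library, and was 310 with the averaged libraries and 0 without the 2 palbociclib libraries that held skin transcripts.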

How the results depend on the processing

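Corrections for length and GC content, the averaging of libraries, and leaving out libraries with lymphoid or skin transcripts were chosen only after the result was seen, as was running the settings without vehicle replicate 2; the others were planned. The cause was not tested unless stated.

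A pseudocount of 0.1 gave 1 gene for palbociclib against vehicle, 13 for the combination against vehicle and 0 for the combination against OPG-Fc. No filter gave 0 for the combination against OPG-Fc and 221 for palbociclib averaged over OPG-Fc, and an FPKM of at least 5 gave 90 for the combination against vehicle. Median-of-ratios scaling gave 0 for the combination against OPG-Fc and 181 for palbociclib averaged. Quantile normalization gave 3 for palbociclib against vehicle, 6 for the combination against vehicle, 0 for the combination against OPG-Fc and 184 for palbociclib averaged. Array weights, whose estimation did not converge in either fit, gave 671 for the combination against palbociclib, 3490 for the combination against OPG-Fc and 0 for palbociclib averaged, with a weight of 0.103 for both vehicle libraries and 12.6 for OPG-Fc replicate 3. The replicate block gave 0 for the combination against OPG-Fc and 7 for palbociclib averaged; only 5 of 15 pairs with the same replicate number had a correlation over 0.1, so the numbers do not pair the samples. Fitting only the groups compared gave 160 for the combination against OPG-Fc.

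Without vehicle replicate 2 the counts were 0 for palbociclib, 1 for OPG-Fc and 8 for the combination against vehicle, 0 for the combination against palbociclib, 615 for the combination against OPG-Fc, and 511 and 452 for palbociclib and OPG-Fc averaged. In that order, array weights gave 1067, 2536, 3136, 738, 3844, 3825 and 3136, and a pseudocount of 0.1 gave 5, 5, 32, 0, 483, 563 and 511. An FPKM of at least 5 gave 3, 3, 29, 53, 402, 530 and 369, and no filter 0, 0, 0, 0, 664, 392 and 283. Quantile normalization gave 1, 2, 19, 0, 284, 460 and 356, median-of-ratios scaling 1, 1, 0, 0, 416, 366 and 324, and the replicate block 0, 0, 0, 0, 203, 33 and 136. No variance trend gave 0, 2, 0, 0, 711, 500 and 475, and a robust prior 0, 4, 9, 0, 683, 567 and 457. Averaged libraries gave 0, 41, 0, 1, 89, 114 and 310, and leaving out both palbociclib libraries with skin transcripts 0, 0, 0, 0, 153, 3 and 0.

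Length correction gave 0 for the combination against OPG-Fc and 60 for palbociclib averaged, and length and GC correction 0 and 195. Leaving out both libraries with lymphoid transcripts gave 1 for palbociclib and 1 for OPG-Fc against vehicle, 116 for the combination against OPG-Fc, 194 for palbociclib averaged and 216 for OPG-Fc averaged. Length correction after leaving out vehicle replicate 2 gave 4 for palbociclib and 5 for the combination against vehicle, 314 for the combination against OPG-Fc and 452 for OPG-Fc averaged. With GC content as well these were 7, 18, 719 and 659, with 41 for the combination against palbociclib and 668 for palbociclib averaged. Averaging libraries with a shared number gave 0 for the combination against OPG-Fc and 0 for palbociclib averaged, as did leaving out both palbociclib libraries with skin transcripts, with fewer samples in each.

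Leaving out 1 library at a time gave 0 to 6802 genes for palbociclib, 0 to 5272 for OPG-Fc and 0 to 6640 for the combination against vehicle, 0 to 143 for the combination against palbociclib, 0 to 623 for the combination against OPG-Fc, 2 to 6927 for palbociclib averaged, 0 to 4012 for OPG-Fc averaged and 0 to 4800 for the interaction. The highest came without vehicle replicate 1, except 143, without palbociclib replicate 2.

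Directions of results that passed in either setting turned as follows, by camera's direction for lists. Without vehicle replicate 1, OPG-Fc against vehicle had medians of -0.169 for macrophage markers, -0.038 for adipocyte markers and 0.353 for type I interferon response genes, which ranged to 0.878, 3.189 and -0.552 without vehicle replicate 2, and Ccne1 was at -0.485 for OPG-Fc averaged, which ranged to 0.497. Without vehicle replicate 2, the senescence-associated secretory genes were at -0.152 for palbociclib against vehicle, Nuak1 at -1.096 for the combination against vehicle, and Perp at -0.87 and the hypoxia and glycolysis genes at -0.308 for OPG-Fc averaged, which ranged to 2.117, 2.647, 2.387 and 0.605 without vehicle replicate 1. The senescence and hypoxia lists were at -0.152 and -0.31 without both lymphoid libraries, -0.27 and -0.326 after length correction without vehicle replicate 2, and -0.207 and -0.357 with GC content as well. Perp was at -0.946 and -0.9 under these corrections, and Nuak1 at -1.04 under the latter. Without the palbociclib libraries with skin transcripts, the combination against palbociclib had medians of 0.009 for basal keratinocyte and 1.163 for skin genes, and the interaction of the skin genes was 0.406; 1 palbociclib library remained, and the 2 were left out because they held skin transcripts. Medians that changed sign while camera's direction did not were all of interferon lists. The type I interferon response genes turned from -0.122 to 0.016 for OPG-Fc against vehicle without OPG-Fc replicate 1, and from -0.219 to 0.021 for OPG-Fc averaged without vehicle replicate 1. For the combination against vehicle they turned from 0.057 to -0.393 without vehicle replicate 2 or both lymphoid libraries, and to -0.364 and -0.247 after the corrections without vehicle replicate 2. The interferon-gamma-inducible genes turned from -0.15 to 0.14 and 0.025 for OPG-Fc against vehicle without vehicle replicate 1 and OPG-Fc replicate 1.

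Over all settings 1210 values of gene lists and 9896 of single genes stayed on their side of the threshold, with their direction where they passed, 109 and 525 no longer passed, 17 and 508 newly passed, and 14 and 6 turned. Of the 109 list values that no longer passed, 43 came from camera with an estimated correlation and 33 from fry. Each was run on 54 values, and camera on ranks left all 54 the same. With all 11 libraries fry called 0 of 35 lists for palbociclib or the combination against vehicle, the combination against palbociclib and the interaction. It called 3 to 5 in the other comparisons. Camera at the preset correlation called 7 to 18 per comparison. The depth is unknown, so what it limits cannot be given.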

Other observations

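The lists and libraries below were chosen after their values were seen.

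Of 7 mast cell markers, 0 passed over all genes in limma for palbociclib against vehicle, and 0 with all 11 libraries and 4 without vehicle replicate 2 rose adjusted over the list alone. Their median log2 fold changes were 0.98 and 1.56 (camera adjusted p = 0.109 and 0.000272; adjusted p = 0.696 and 0.543 with an estimated correlation). Without palbociclib replicate 2 the median was 1.30 (adjusted p = 0.0137). The mast cell protease gene Cma1 was at 0.98 ± 0.58 and 1.94 ± 0.53 (SE). In palbociclib replicates 1 and 3, which held skin transcripts, the list had a mean log2(FPKM + 1) of 3.02 and 2.88. Palbociclib replicate 2 was at 1.94. Vehicle replicate 1 was the lowest library at 1.27, and vehicle replicate 2 was at 2.47. The OPG-Fc and combination libraries lay at 2.16 to 2.69 and 1.83 to 2.74. The 28 interferon-gamma-inducible genes had medians of -0.15 and -0.47 for OPG-Fc against vehicle (camera adjusted p = 0.0219 and 2.96e-05; adjusted p = 0.758 and 0.77 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Cxcl10, a chemokine gene, was at -0.15 ± 0.26 and -0.59 ± 0.23. The list was at 0.14 without vehicle replicate 1 (adjusted p = 0.858) and 0.03 without OPG-Fc replicate 1 (adjusted p = 0.615), and at -0.26 and -0.34 without OPG-Fc replicates 2 and 3. It also lost its call after quantile normalization (-0.25, adjusted p = 0.168), length correction (-0.31, adjusted p = 0.0797) and length and GC correction (-0.23, adjusted p = 0.11).

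Skeletal muscle markers had a median FPKM of 0.06 and 0.4 in the vehicle libraries and 0.9 to 21.9 in the 9 treated libraries. Acta1, the skeletal muscle actin gene, had an FPKM of 0.06 and 0.1 in the vehicle libraries and 9.43 to 151 in the treated ones.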
